A study of Mus musculus with 57 samples.

How the data were processed

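The samples were 57 regions of mouse pancreas profiled with the GeoMx Whole Transcriptome Atlas, 7 from untreated controls and 50 from 9 time points of caerulein pancreatitis. Per the labels the tissue was laid out in 2 tissue arrays, each holding every time point. The region's time point was read from the labels, and its array from its sample name. Regions were joined to the columns of the tables by that name, with 0 columns left unmatched.

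Per the file headers, GeoMx NGS Pipeline 2.3.3.10 turned the sequencing reads into deduplicated counts of each probe barcode, and these barcode counts were deposited for each region with 20175 barcodes. The authors also deposited a table of 9780 targets in expected counts, which are the deduplicated counts of each target, averaged over probes for the negative-probe value and for 3 targets with 2 probes. Of its values, those of 9777 single-probe targets were whole numbers to within 1e-06 and equal to 1 barcode of the region files in all 57 regions. The 10398 barcodes not paired with a target were not analysed here. A second deposited table holds the same values as a normalised signal, each region multiplied by 1 factor so that its 75th percentile is 136.81. It was used here only to recompute the control levels as ratios to the negative probes. The deposited region summary gives reads and nuclei as counts per region, the sequencing saturation in percent (94.6 to 96.3 percent) and the normalisation factor as a ratio. The filters the authors applied to probes and targets, and the role of limma and of the genome build mm10 that the labels name, are not given in the sources used here. Probe positions are those of the annotation on GRCm38.p6 as the file gives them.

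Depth was taken from the files. Raw reads per region ran from 36264864 to 167668771 (median 74926976), deduplicated reads from 1526575 to 6998005 and target counts from 1036609 to 5035487. The negative-probe value ran from 42.1 to 186 counts, and 480 to 2679 targets per region exceeded 2 times that value. Counting error is small for abundant targets. Most targets lay near background, where a difference between groups is hard to detect. The deposited limit of quantitation was 1.47 to 1.65 times the negative value and left 1942 to 6041 targets per region above it.

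The labels do not tie regions to animals, and regions of one time point on one array probably share a piece of tissue. The counts of the regions of one time point on one array were therefore added, giving 20 sums of 1 to 4 regions. Fractional values were rounded. A target was tested if it exceeded 2 times the negative-probe value in at least 3 of the 57 regions, which left 2688 genes. The plan fixed this criterion for the case in which single negative probes are not given. Otherwise it set the geometric mean times the squared geometric SD of the negative probes. Here the single negative probes were not matched to barcodes, so the first criterion was taken. The deposited limit of quantitation served only as an alternative filter. The sums were scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, with terms for group and array and 9 residual degrees of freedom). The common dispersion was 0.0122, a biological coefficient of variation of 0.111, with 8.26 prior degrees of freedom. Each of the 9 time points was compared with control, 72 hours with 12 hours and 30 days with 72 hours, and the 9 time terms were tested together for any change. Genes at a Benjamini-Hochberg adjusted p under 0.05 were called, and each SE is the absolute log2 difference divided by the square root of its F statistic. Because 2 sums make a group, the p-values rest on spread pooled over all groups.

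Before the data were examined, 23 gene lists for acinar, ductal, islet, immune, stromal, stress and metabolic genes were fixed, together with the tests, most alternatives and the rule for named genes. Of these lists 16 had at least 3 genes tested and were tested in 11 comparisons, 176 tests adjusted together, with camera of limma 3.58.1 at a preset correlation of 0.01. Camera with an estimated correlation and fry were the alternatives. Beside the calls over all genes, calls adjusted over the list alone are given. The rule named, at each time, up to 8 rises and 8 falls with the largest log2 difference among called genes with the same sign on both arrays, and up to 4 called members of each list with the largest absolute difference. In the control it named the 10 highest targets. Members of the lists could be named at any time. The result of 1 list member between 12 and 72 hours is not reported. Values outside the rule, chosen after they were seen, are those of Nr1d2 at 3 hours and 14 days, of Gm10334 at 3 and 12 hours, of Amy2a1, Gm10334 and H4c17 between 72 hours and 30 days, and of the set of replication-dependent histone genes.

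Levels per region are CPM after TMM, as mean ± SD over regions. Nuclei per region were compared with control by 2-sided exact permutation tests over regions, adjusted over the 9 times. The edgeR fit was tested on simulated data with the counts and design of these sums. It recovered 57 of 67 genes changed 1.5-fold, 66 of 67 changed 2-fold and 66 of 66 changed 4-fold, and 8 of 197 calls were false. It called 0 genes in an unchanged contrast. For a changed list the adjusted p was 1.85e-08 with camera, 0.00967 with an estimated correlation and 0.0136 with fry. Of 165 tests of unchanged lists camera called 6 and the estimated correlation 0. These rates hold for the simulated data only. How correlation between genes or a difference between the arrays would change them was not tested.

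The alternatives chosen in advance were scaling by the 75th percentile, by DESeq2 size factors and by total counts, no filter and a stricter filter (20 regions, 899 genes), no array term, DESeq2 1.42.0, subtraction of the negative-probe level with limma, each region as a sample with no block, with the replicate number as a block or with time and array as a random block, and leaving out each sum. For any change, DESeq2 used the likelihood ratio test in place of the Wald test chosen in advance. Chosen after seeing the data were a filter at the deposited limit of quantitation (8530 genes), scaling to the negative probes, leaving out the Lrr1 target and leaving out the 12-hour region with the highest Ins2 count. Of 55 regions with a partner at the same time on the same array, 55 had as nearest region one of the same time point. Among 142 pairs of regions of 1 group none had the same counts (lowest chi-square per degree of freedom 1.23). Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.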

Results

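RNA targets were counted in 57 regions of formalin-fixed mouse pancreas with the GeoMx Whole Transcriptome Atlas. In this assay barcoded probes bind RNA in a tissue section, light releases the barcodes of a chosen region, and the barcodes are counted by sequencing. The regions were squares about 650 µm on a side (421366 µm²), except the 72-hour region of array 1, which covered 509054 µm². The C57BL/6 mice were untreated or had pancreatitis caused by caerulein, an analogue of cholecystokinin that overstimulates the enzyme-secreting acinar cells. There were 7 control regions, 3 regions at 3 hours, 6 at 12 hours, 6 at 24 hours, 5 at 48 hours, 4 at 72 hours, 6 at 5 days, 6 at 7 days, 7 at 14 days and 7 at 30 days. The event from which these times run is not given in the sources used here. Each group had regions on both of the 2 tissue arrays. The labels do not tie regions to animals, and regions of one time point may share an animal and a piece of tissue, so the counts of a time point were added within each array. The resulting 20 sums, 2 per group, were the samples of each comparison, and the p-values measure only the spread between these samples.

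The total target count per region ran from 1036609 to 5035487 with a median of 2036021. Array 2 was the deeper, with a median of 2353798 against 1766301 on array 1. The sums ran from 1036609 counts, at 72 hours on array 1, to 9850356, in the control on array 2, and the sums of 3 hours and 72 hours on array 1 held 1 region each. The signal of the 209 averaged negative probes, which match no transcript and so measure background, ran from 42.1 to 186 counts per region. The number of targets above 2 times that background was 645 ± 103 (SD, n = 7) in control regions, 1679 ± 275 (n = 6) at 12 hours, 1760 ± 486 (n = 6) at 24 hours and 730 ± 110 (n = 7) at 30 days. Nuclei per region numbered 942 ± 242 in control and 1626 ± 263 (SD, n = 5) at 48 hours.

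**Figure D1:**
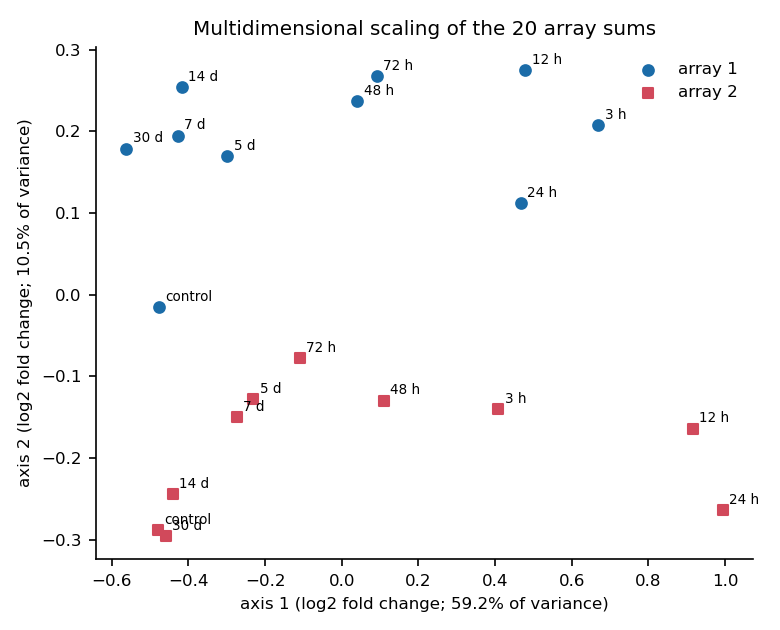
Multidimensional scaling of the 20 sums, with both axes in log2 fold change and 1 point per time point and array. Axis 1 held 59.2% of the variance and runs from the control and late sums to those of 3, 12 and 24 hours, and axis 2, with 10.5%, parts the sums of array 1 from those of array 2.

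The untreated pancreas was described first, as the level from which the courses start. Acinar products were 7 of its 10 highest targets: Cela2a, a pancreatic elastase gene, stood at 95898 ± 20119 normalised counts (CPM; SD, n = 7), the chymotrypsinogen gene Ctrb1 at 56253 ± 8403, the amylase target Amy2a1 at 52733 ± 16794 and the pancreatic lipase gene Pnlip at 32781 ± 2771. Cela3b, Cel and the trypsinogen gene 2210010C04Rik followed at 28451 ± 6268, 23302 ± 4537 and 22951 ± 2255. Pnlip lay 424 ± 40.8 times above the negative probes. The highest count belonged to Lrr1, whose probe maps to chromosome 12, 69168867 to 69168902 (GRCm38.p6), with 18.2 ± 3.83% of all counts. Whether this probe also binds other RNA in the pancreas was not tested. The predicted genes Gm10265 and Gm52523 were also among the 10 highest targets. In most control regions 22 of the 24 measured digestive enzyme genes and 61 of the 74 ribosomal protein genes exceeded 2 times background. The same held for 2 of 14 islet, 1 of 18 ductal, 0 of 18 macrophage and 0 of 24 fibroblast and matrix genes. The rest of these lists did not exceed that level in most control regions. Some of them still lay above the deposited limit of quantitation, such as Krt8 at 1.93 ± 0.26 times the negative probes.

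The changes that follow are relative to the middle of all genes. With trimmed-mean (TMM) scaling, the median log2 difference of all 2688 tested genes lay between -0.021 at 3 hours and 0.0065 at 72 hours. Scaling to the total count alone moved that median to 0.53 at 3 hours, 0.75 at 12 hours, 0.81 at 24 hours, 0.74 at 48 hours, 0.65 at 72 hours, 0.43 at 5 days, 0.38 at 7 days, 0.22 at 14 days and 0.15 at 30 days. Scaling to the negative probes moved it to 0.20, 0.40, 0.44, 0.13 and 0.13 at the times from 3 to 72 hours. The 75th percentile moved it to 0.14 at 12 hours and 0.15 at 24 hours. With the background subtracted it stood at 0.30, 0.55, 0.56, 0.20 and 0.23 from 3 to 72 hours and at 0.14 at 5 days. Scaled by TMM, the negative probes themselves differed from control by -0.26, -0.41 and -0.43 on the log2 scale at 3, 12 and 24 hours and by -0.16 to -0.035 later.

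Over the 9 time points, 1131 of the 2688 genes differed between any of the groups (edgeR, adjusted p under 0.05). The first 24 hours held most of the calls against control, and from 5 days on at most 10 genes were called at a time. By the mean of each list, digestive enzymes were lowest at 24 hours, ductal markers and regenerating proteins were highest within the first 12 hours, and matrix and macrophage genes were highest at 24 hours. Single genes departed from this, such as Clps and Lgals3, which lay furthest from control at 3 hours. Where the control level of a gene lay under 2 times the negative probes, much of its control count is background, and its rise is given as a log2 difference in counts without a fold. Reg3b lay at 1.55 ± 0.14 times the negative probes in control (SD, n = 7), Krt8 at 1.93 ± 0.26, Krt18 at 1.55 ± 0.17, Col1a1 at 1.48 ± 0.21 and Col3a1 at 1.38 ± 0.12. The differences below are log2 values ± SE from the sums of 2 arrays per group (n = 2), and the mean of a list is the mean log2 difference of its tested genes.

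**Figure D2:**
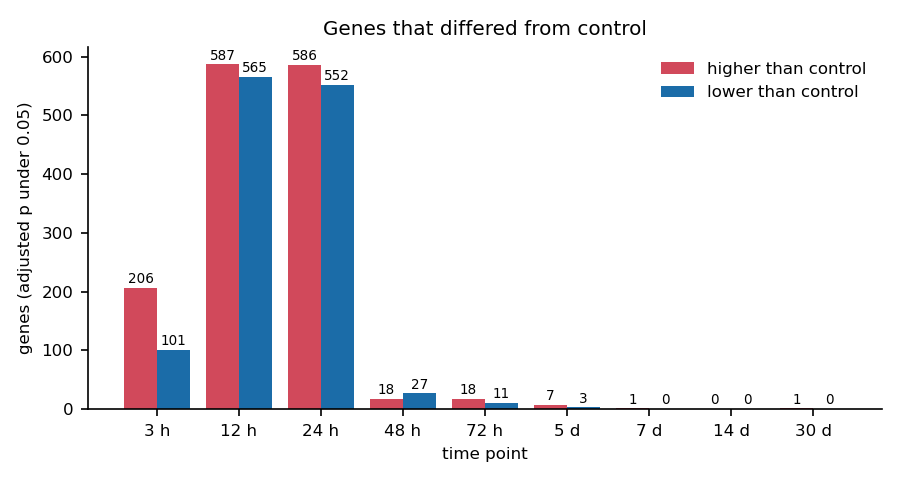
Genes higher (red) and lower (blue) than control at each of the 9 time points, as counts of genes with an adjusted p under 0.05 in edgeR. The counts were 587 higher and 565 lower at 12 hours, 18 higher and 27 lower at 48 hours, and 0 of either at 14 days.

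The earliest comparison, 3 hours against control, asked what differed at the first time sampled. Transcripts of acinar secretory products were lower in the regions, whose mix of cells was not resolved: the colipase gene Clps lay -3.93 ± 0.51 from control, the pancreatic ribonuclease gene Rnase1 -3.60 ± 0.53, the chymotrypsin gene Ctrc -3.32 ± 0.30, Pnlip -3.08 ± 0.65 and Cela2a -2.97 ± 0.51. Over the same interval keratins of simple epithelia rose, Krt8 by 4.39 ± 0.41 (adjusted p = 2.51e-06) and Krt18 by 3.65 ± 0.34, together with Clu, which encodes the extracellular chaperone clusterin, at 4.84 ± 0.55. Reg3b, a secreted lectin of the injured pancreas, rose by 5.33 ± 0.74 (adjusted p = 1.15e-04) and its relative Reg2 rose 17.4-fold. The largest rise was that of 1810009J06Rik, a trypsin-like gene of the trypsinogen cluster on chromosome 6, at 5.49 ± 0.63. Its probe maps to 40968273 to 40968314 in that gene and to 40995946 to 40995987 in Gm2663, so its counts cannot be assigned to 1 of the pair.

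Of the 22 tested digestive enzyme genes 20 fell at 3 hours and 0 rose, with 21 lower when adjusted over the list alone (mean -2.13, camera adjusted p = 8.27e-24, adjusted p = 0.465 with an estimated correlation). Among 10 acinar transcription factor and secretory genes, 5 fell and 1 rose, and 7 were lower and 1 higher adjusted over the list alone (mean -0.51, camera adjusted p = 1.43e-04, adjusted p = 0.556 with an estimated correlation). The list mean turned to 0.016 with total-count scaling. Those that fell included Pdia2, a pancreatic disulfide isomerase, at -2.54 ± 0.31, Cckar, the receptor through which caerulein acts, at -1.04 ± 0.20, and Gnmt at -0.98 ± 0.13, while the stress-response gene Nupr1 rose by 1.82 ± 0.38. Ductal and metaplasia markers rose in 8 of 14 cases and in 10 adjusted over the list alone (mean 1.72, camera adjusted p = 6.66e-16, adjusted p = 0.465 with an estimated correlation). Spp1, which encodes osteopontin, lay at 2.88 ± 0.39. Heat shock genes rose in 4 of 7 cases, 5 adjusted over the list alone (mean 0.88, camera adjusted p = 3.66e-05, adjusted p = 0.544 with an estimated correlation). Hsp90ab1 lay at 1.63 ± 0.27, Hspa8 at 1.58 ± 0.34 and Hspb1 at 1.46 ± 0.21. Of 5 immediate early genes 3 rose, also 3 adjusted over the list alone (mean 0.60, camera adjusted p = 6.82e-04, adjusted p = 0.544 with an estimated correlation). These were Btg2 at 1.29 ± 0.15, Junb at 0.69 ± 0.21 and Klf6 at 0.63 ± 0.16. The cytoskeletal genes Tmsb4x and Actb rose by 3.01 ± 0.41 and 2.99 ± 0.39.

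Regenerating and trefoil genes gave 4 rises and 1 fall among 7 at 3 hours, the same adjusted over the list alone (mean 1.57, camera adjusted p = 0.00853, adjusted p = 0.688 with an estimated correlation). The fall was that of the trefoil gene Tff2 at -2.67 ± 0.33, and Reg3g rose by 2.16 ± 0.30. Fibroblast and matrix genes rose in 4 of 16 cases, 5 adjusted over the list alone (mean 0.36, camera adjusted p = 0.0327, adjusted p = 0.725 with an estimated correlation). Sparc lay at 1.00 ± 0.24 and Col3a1 at 0.97 ± 0.30. Ribosomal protein genes rose in 5 of 74 cases and in 0 adjusted over the list alone (mean 0.50, camera adjusted p = 6.97e-09, adjusted p = 0.704 with an estimated correlation). Rps20 lay at 0.97 ± 0.28 and Rps16 at 0.95 ± 0.30. Of 15 endoplasmic reticulum stress genes 4 fell, 6 adjusted over the list alone, including Sel1l at -1.15 ± 0.26, Herpud1 at -1.13 ± 0.27 and Edem1 at -1.07 ± 0.22, and the list as a whole was not called (camera adjusted p = 0.0577). The macrophage marker Lgals3 rose by 1.38 ± 0.12, 1 of 10 on its list, and the list was not called (camera adjusted p = 0.0577). The 2 tested adipocyte markers split, with Fabp4 at 0.51 ± 0.16 and Cfd at -0.77 ± 0.19. The NF-kappaB subunit gene Relb, 1 of 6 tested cytokine and NF-kappaB genes to be called, lay at -0.35 ± 0.10 but at 0.18 with total-count scaling.

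At 3 hours 206 genes were higher and 101 lower of 2688 tested, and the 307 calls had the same sign on both arrays. The higher share moved with the scaling: 283 of 356 by the 75th percentile, 400 of 452 to the negative probes, 461 of 543 with the background subtracted and 1527 of 1558 by total counts. Of the 101 falls 68 exceeded the fall of the negative probes by more than 2 SE. Without the control sum of array 1 there were 188 calls, without that of array 2 there were 151, and without the 3-hour sums of array 1 and array 2 there were 118 and 472.

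The comparison of 12 hours with control came next. Pnlip had fallen 16.8-fold (-4.07 ± 0.68, adjusted p = 4.37e-04, with -3.31 on array 1 and -5.33 on array 2), and the zymogen granule gene Zg16 stood at -3.82 ± 0.56, Clps at -3.64 ± 0.50, Cel at -3.50 ± 0.59 and Cela2a at -3.45 ± 0.53. Reg3b had its highest value of the course at 5.80 ± 0.76, as did Clu, 34.9-fold (5.12 ± 0.56). Stromal transcripts were higher than control, with the collagen genes Col1a1 at 2.38 ± 0.37 and Col3a1 at 2.16 ± 0.30. Ribosomal protein genes that rose included Rps6, by 1.40 ± 0.30, and Rpl5, by 1.37 ± 0.26.

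Of 22 digestive enzyme genes 21 fell at 12 hours, likewise 21 adjusted over the list alone (mean -2.40, camera adjusted p = 4.58e-17, adjusted p = 0.544 with an estimated correlation). The list mean was -1.93 on array 1 and -2.96 on array 2. Ductal and metaplasia markers rose in 10 of 14 cases, 11 adjusted over the list alone (mean 1.31, camera adjusted p = 1.49e-05, adjusted p = 0.645 with an estimated correlation). Spp1 lay at 3.04 ± 0.39, Krt8 at 2.53 ± 0.38 and Krt18 at 2.27 ± 0.32. Fibroblast and matrix genes rose in 11 of 16 cases, the same adjusted over the list alone (mean 0.79, camera adjusted p = 3.06e-05, adjusted p = 0.645 with an estimated correlation). Sparc lay at 1.51 ± 0.23 and Postn, the matrix protein periostin, at 0.99 ± 0.29. Ribosomal protein genes rose in 57 of 74 cases, 65 adjusted over the list alone (mean 0.77, camera adjusted p = 8.15e-13, adjusted p = 0.688 with an estimated correlation). Immediate early genes rose in 4 of 5 cases, again 4 adjusted over the list alone (mean 0.61, camera adjusted p = 0.0107, adjusted p = 0.645 with an estimated correlation). Btg2 lay at 1.06 ± 0.14 and Junb at 0.97 ± 0.19. Macrophage markers rose in 3 of 10 cases, 3 adjusted over the list alone (mean 0.35, camera adjusted p = 0.0464, adjusted p = 0.700 with an estimated correlation). They were the cathepsin gene Ctss at 0.90 ± 0.17, the complement gene C1qb at 0.77 ± 0.17 and Lgals3 at 0.65 ± 0.11. Among 10 acinar transcription factor and secretory genes 5 fell and 3 rose, the same adjusted over the list alone (mean -0.39, camera adjusted p = 0.0292, adjusted p = 0.688 with an estimated correlation). Their mean turned to 0.36 with total-count scaling and 0.023 when scaled to the negative probes. Pdia2 lay at -2.95 ± 0.31 and Gnmt at -1.54 ± 0.12, while the secretory transcription factor Xbp1 lay at 0.96 ± 0.21.

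The other lists were not called as a whole at 12 hours. Of 7 regenerating and trefoil genes 4 rose and 1 fell, 5 and 1 adjusted over the list alone (camera adjusted p = 0.0558). Reg2 lay at 4.14 ± 0.72, Reg3g at 2.79 ± 0.30 and Tff2 at -3.43 ± 0.34. Heat shock genes rose in 4 cases and fell in 1 of 7 (camera adjusted p = 0.171). Hspa8 lay at 1.53 ± 0.33 and the falling Hsph1 at -0.57 ± 0.16, which lay at 0.20 with total-count scaling. Endoplasmic reticulum stress genes went both ways, 3 rising and 4 falling of 15 (camera adjusted p = 0.594). The chaperone genes Calr and Pdia3 lay at 0.69 ± 0.19 and 0.62 ± 0.22, and Herpud1 and Edem1 at -0.68 ± 0.23 and -0.65 ± 0.21, the last 2 being above 0 with total-count scaling. Oxidative phosphorylation genes rose in 5 of 13 cases (camera adjusted p = 0.241), for example Atp5a1 at 0.59 ± 0.14. Of the cytokine and NF-kappaB list, Lcn2, the lipocalin of acute inflammation, rose by 0.89 ± 0.27, and the inhibitor gene Nfkbia lay at -0.36 ± 0.11, but above 0 by total counts and by the negative probes. The 2 called neutrophil markers of 3, Il1r2 at -0.45 ± 0.11 and Retnlg at -0.31 ± 0.096, also turned positive by total counts, and Retnlg by the negative probes too. Stmn1, a microtubule regulator of dividing cells, rose by 0.52 ± 0.12, and 0 of 3 cholesterol synthesis genes were called. The haemoglobin gene Hba-a1, the single tested erythrocyte marker, lay at -1.43 ± 0.45.

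Islet transcripts at 12 hours were highest in 1 region of array 1. Ins2 lay at 4.12 ± 0.82, Ins1 at 2.66 ± 0.56, Iapp at 1.96 ± 0.45 and the glucagon gene Gcg at 1.23 ± 0.44. There were 4 rises and 2 falls among 6 islet markers (camera adjusted p = 0.485). The list mean was 2.08 on array 1 against 0.24 on array 2. With the islet-rich region of array 1 left out, as chosen after seeing the data, Ins2 lay at 0.86, Ins1 at 0.64, Iapp at 0.19 and Gcg at 0.042, and none of these 4 was called (adjusted p between 0.077 for Ins2 and 0.94 for Gcg in edgeR).

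At 12 hours 587 genes were higher and 565 lower, and 1151 of the 1152 calls had the same sign on both arrays. The 75th percentile gave 925 higher of 1150 (812 genes shared with TMM), the negative probes 1603 of 1654, background subtraction 943 of 1088 and total counts 2193 of 2223, and 72 of the 565 falls exceeded the fall of the negative probes by more than 2 SE. There were 402 calls without the control sum of array 2 and 280 without the 12-hour sum of array 2.

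The comparison of 24 hours with control held the lowest mean of the enzyme list. Pnlip was 46.6-fold lower (-5.54 ± 0.73, adjusted p = 4.30e-05), with -4.75 on array 1 and -6.91 on array 2, at 703 ± 505 CPM (SD, n = 6 regions) against 32781 in control, Cela2a was 20.2-fold lower (-4.34 ± 0.55) and the trypsinogen gene 2210010C04Rik 17.8-fold lower (-4.16 ± 0.47). The matrix genes Col1a1 and Col3a1 had their highest values, 3.45 ± 0.39 and 2.98 ± 0.31. Apoe, the lipid carrier made by macrophages among other cells, rose by 3.85 ± 0.43. Reg3b stayed high at 5.30 ± 0.74, Clu stood 18.3-fold above control and 1810009J06Rik at 3.46 ± 0.57.

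Of 22 digestive enzyme genes 21 fell at 24 hours, 21 also adjusted over the list alone (mean -2.93, camera adjusted p = 9.67e-24, adjusted p = 0.465 with an estimated correlation). The list means were -2.27 on array 1 and -3.81 on array 2. Cela1 stood at -3.94 ± 0.44, Ctrl at -3.74 ± 0.57, Zg16 at -4.17 ± 0.57 and Cel at -4.01 ± 0.60. Fibroblast and matrix genes rose in 15 of 16 cases and in 16 adjusted over the list alone (mean 1.29, camera adjusted p = 5.55e-13, adjusted p = 0.465 with an estimated correlation). Sparc lay at 2.40 ± 0.24 and Postn at 2.15 ± 0.29. Macrophage and monocyte markers rose in 8 of 10 cases, the same adjusted over the list alone (mean 0.69, camera adjusted p = 3.29e-05, adjusted p = 0.645 with an estimated correlation). The list mean was 0.45 on array 1 and 0.86 on array 2, where 1 region stood apart at a mean log2 CPM of 7.91 against 6.95 to 7.23 in the other 24-hour regions. C1qb lay at 1.39 ± 0.17, C1qa at 0.84 ± 0.14, Ctss at 1.32 ± 0.17 and the lysozyme gene Lyz2 at 0.97 ± 0.13. In most 24-hour regions 12 of 24 matrix genes and 7 of 18 macrophage genes exceeded 2 times background. Ductal and metaplasia markers rose in 9 of 14 cases, 9 adjusted over the list alone (mean 1.13, camera adjusted p = 4.30e-04, adjusted p = 0.688 with an estimated correlation), Spp1 by 2.74 ± 0.39 and Krt8 by 1.88 ± 0.37. All 5 immediate early genes rose, 5 adjusted over the list alone (mean 0.65, camera adjusted p = 0.00498, adjusted p = 0.645 with an estimated correlation), Btg2 by 0.87 ± 0.14 and Jun by 0.49 ± 0.10. Ribosomal protein genes rose in 58 of 74 cases, 64 adjusted over the list alone (mean 0.72, camera adjusted p = 1.05e-10, adjusted p = 0.700 with an estimated correlation), Rps16 by 1.27 ± 0.29 for example. Acinar transcription factor and secretory genes fell in 4 of 10 cases, 4 adjusted over the list alone (mean -0.50, camera adjusted p = 0.00613, adjusted p = 0.645 with an estimated correlation). Pdia2 lay at -2.95 ± 0.31 and the acinar water channel gene Aqp12 at -0.99 ± 0.15, but the list mean turned to 0.28 with total-count scaling.

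The remaining lists were not called at 24 hours. Regenerating and trefoil genes rose in 4 cases and fell in 1 of 7 (camera adjusted p = 0.303). Reg2 lay at 3.22 ± 0.70, Reg3g at 2.57 ± 0.30 and Tff2 at -3.75 ± 0.35. Stmn1, at 1.19 ± 0.12, was the 1 called gene of 4 proliferation genes. Among endoplasmic reticulum stress genes Pdia3 rose by 1.00 ± 0.22, Calr by 0.69 ± 0.19 and Canx by 0.60 ± 0.16, while 4 of the 15 genes on that list fell (camera adjusted p = 0.970). Heat shock genes gave 4 rises and 1 fall (camera adjusted p = 0.209), Hspa8 lying at 1.52 ± 0.33, and the falling Hsph1 turned positive by total counts and by the negative probes. Oxidative phosphorylation genes rose in 4 of 13 cases (camera adjusted p = 0.432), Cox4i1 by 0.45 ± 0.13. Of 6 islet markers the prohormone convertase gene Pcsk1 lay at -0.83 ± 0.18 and Mafa at -0.42 ± 0.12 (camera adjusted p = 0.365), and Mafa turned positive by total counts and by the negative probes. The same 2 scalings turned Il1r2, at -0.40 ± 0.11, and Retnlg, at -0.34 ± 0.097, 2 of 3 neutrophil markers (camera adjusted p = 0.236). Insig1 at -0.46 ± 0.15, 1 of 3 cholesterol synthesis genes, and Cfd at -0.81 ± 0.16 were positive by total counts. Nfkbiz, at 0.38 ± 0.11, was the 1 called gene of 6 cytokine and NF-kappaB genes. The interferon-stimulated gene Bst2, at 0.037 ± 0.12, and the endothelial marker Eng, at 0.033 ± 0.13, the single tested members of their lists, were not called. Among the targets were 3 T and NK cell, 6 B and plasma cell and 6 tuft cell markers. The last include Mydgf, which was not on the fixed list and was matched only through a synonym. Of the markers of these 3 lists 0 passed the filter on low counts. Any gene of these lists that was not among the targets could not be tested, so absence of these cells cannot be concluded.

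At 24 hours 586 genes were higher and 552 lower, and the 1138 calls had the same sign on both arrays. The 75th percentile gave 917 higher of 1147 (816 genes shared with TMM), the negative probes 1724 of 1773, background subtraction 955 of 1093 and total counts 2277 of 2306, and 60 of the 552 falls exceeded the fall of the negative probes by more than 2 SE. There were 478 calls without the control sum of array 2 and 256 without the 24-hour sum of array 2.

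**Figure D3:**
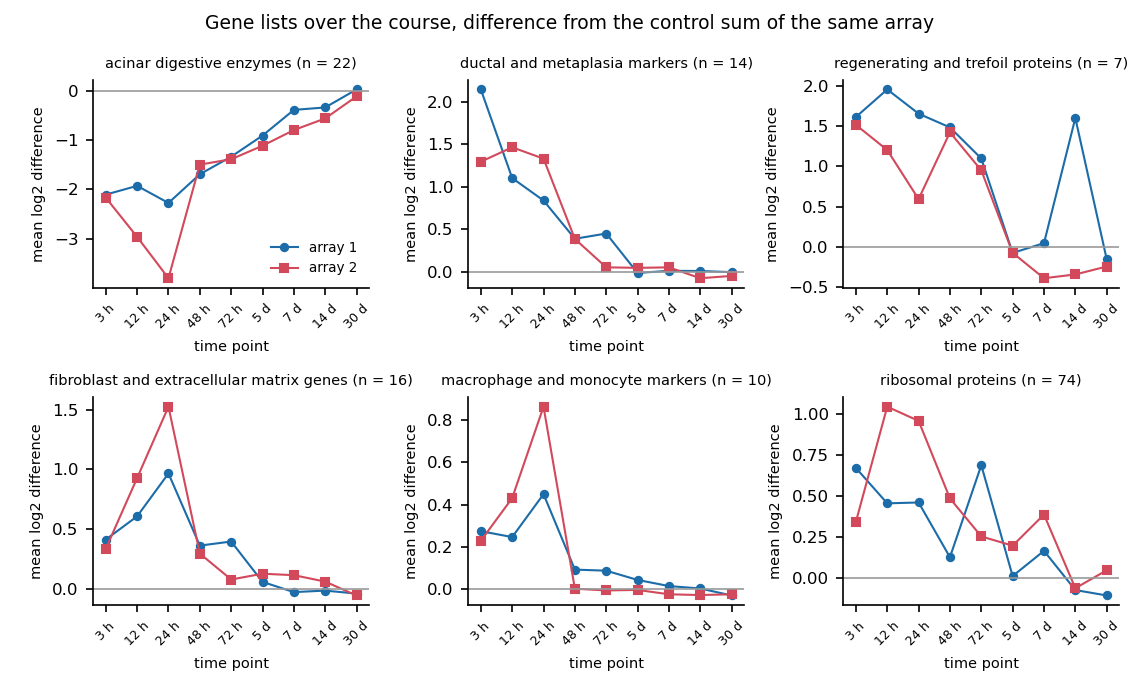
Mean log2 difference of 6 gene lists from the control sum of the same array, against time point, with 1 line per array and the number of tested genes in each title. Digestive enzymes had a mean of -2.27 on array 1 and -3.81 on array 2 at 24 hours, and at 14 days the regenerating and trefoil genes stood at 1.60 on array 1 and -0.35 on array 2.

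By 48 hours fewer genes were called against control, secretory, regenerating and histone genes among them. Pnlip remained at -3.02 ± 0.65, Cela2a at -2.84 ± 0.51, the amylase target Amy2a1 at -2.74 ± 0.51 and the granule protein gene Sycn at -2.38 ± 0.40. Reg3b was still higher by 4.71 ± 0.72 (adjusted p = 0.00152), Reg2 at 3.83 ± 0.71 and Clu at 2.06 ± 0.49. The trypsin-like targets 1810009J06Rik and Gm10334 rose by 4.11 ± 0.59 and 3.66 ± 0.66, the matrix Gla protein gene Mgp by 2.26 ± 0.26 and the replication-dependent histone gene H4c17 by 1.95 ± 0.24.

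Of 22 digestive enzyme genes 9 fell at 48 hours and 18 adjusted over the list alone (mean -1.58, camera adjusted p = 2.51e-28, adjusted p = 0.465 with an estimated correlation). Cela1 lay at -2.27 ± 0.40, Ctrc at -2.07 ± 0.27 and the granule membrane gene Gp2 at -1.86 ± 0.35. Regenerating and trefoil genes rose in 3 cases and fell in 1 of 7, 5 and 1 adjusted over the list alone (mean 1.45, camera adjusted p = 3.66e-05, adjusted p = 0.645 with an estimated correlation). Reg3g lay at 1.99 ± 0.30 and Tff2 at -2.53 ± 0.33. Ribosomal protein genes had 0 calls of 74, 0 also adjusted over the list alone, but a higher mean (mean 0.31, camera adjusted p = 1.47e-09, adjusted p = 0.704 with an estimated correlation). Fibroblast and matrix genes likewise had 0 calls of 16 and 5 rises adjusted over the list alone (mean 0.33, camera adjusted p = 2.02e-04, adjusted p = 0.645 with an estimated correlation). Among ductal markers Clu was the 1 called of 14, with 3 adjusted over the list alone (mean 0.39, camera adjusted p = 0.0136, adjusted p = 0.725 with an estimated correlation). Acinar transcription factor and secretory genes fell in 2 of 10 cases, 3 adjusted over the list alone (mean -0.39, camera adjusted p = 3.81e-04, adjusted p = 0.645 with an estimated correlation). They were Pdia2 at -1.26 ± 0.29 and Gnmt at -0.65 ± 0.11, and total-count scaling turned both Gnmt and the list mean. The immediate early gene Gadd45b rose by 0.59 ± 0.10, 1 of 5 (mean 0.25, camera adjusted p = 0.0102, adjusted p = 0.645 with an estimated correlation), and Stmn1 by 0.55 ± 0.12.

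At 48 hours edgeR called 18 genes higher and 27 lower, with 381 at an unadjusted p under 0.05. DESeq2 called 117, the 75th percentile gave 22 higher of 39, background subtraction 34 of 49, the negative probes 13 of 26 and total counts 2476 of 2494. Without the control sums of array 1 and array 2 there were 26 and 10 calls, and without the 48-hour sums 19 and 15.

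At 72 hours against control enzyme transcripts were still low, with Amy2a1 at -2.70 ± 0.51, Cela2a at -2.32 ± 0.50, Sycn at -2.32 ± 0.40, Gp2 at -2.05 ± 0.35, Cela1 at -1.89 ± 0.40, Ctrc at -1.88 ± 0.28 and the trypsinogen gene Prss2 at -1.76 ± 0.37. Other trypsin-like targets were higher, 1810009J06Rik by 4.29 ± 0.59 (adjusted p = 8.68e-04) and Gm10334 17.2-fold (4.10 ± 0.67). Histone genes were among the rises, with H4c17 at 2.58 ± 0.25, H4c11 at 1.65 ± 0.20 and H3c1 at 1.49 ± 0.24. Their probes have 3, 2 and 4 annotated positions, so these counts cannot be assigned to single genes. Reg3b lay at 3.30 ± 0.68, Reg3g at 1.29 ± 0.30, Apoe at 1.79 ± 0.41 (2.52 in the single region of array 1 and 0.70 on array 2) and Tff2 at -1.87 ± 0.32.

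Of 22 digestive enzyme genes 8 fell at 72 hours, 15 adjusted over the list alone (mean -1.35, camera adjusted p = 4.14e-25, adjusted p = 0.465 with an estimated correlation). Regenerating and trefoil genes rose in 2 cases and fell in 1 of 7, 4 and 1 adjusted over the list alone (mean 1.03, camera adjusted p = 0.00426, adjusted p = 0.688 with an estimated correlation). Ribosomal protein genes had 0 calls of 74 and 7 rises adjusted over the list alone (mean 0.47, camera adjusted p = 2.24e-19, adjusted p = 0.648 with an estimated correlation). The fibroblast and matrix list (mean 0.22, camera adjusted p = 0.0363, adjusted p = 0.725 with an estimated correlation) and the heat shock list (mean 0.29, camera adjusted p = 0.0465, adjusted p = 0.688 with an estimated correlation) had higher means with 0 called genes. The matrix list stood at 0.39 in the single region of array 1 and 0.076 on array 2. The heat shock list stood at 0.49 and 0.14. The acinar transcription factor and secretory list had a lower mean with 0 called genes of 10 and 2 falls adjusted over the list alone (mean -0.34, camera adjusted p = 0.00387, adjusted p = 0.645 with an estimated correlation), which total-count scaling turned. Stmn1 rose by 0.62 ± 0.13 and Gadd45b by 0.50 ± 0.11.

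At 72 hours edgeR called 18 genes higher and 11 lower, with 340 at an unadjusted p under 0.05. DESeq2 called 81, background subtraction gave 49 higher of 58, and total counts 2267 of 2281. Without the control sums of array 1 and array 2 there were 16 and 5 calls, and without the 72-hour sums 18 and 61.

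The comparisons of 5 and 7 days with control followed the later tissue. Gm10334 had its highest value of the course at 5 days, 45.2-fold above control (5.50 ± 0.72, adjusted p = 5.11e-04), and was the 1 gene called at 7 days (4.21 ± 0.67, adjusted p = 0.0217). Its level was 25734 ± 5251 CPM at 5 days (SD, n = 6 regions) against 537 ± 181 in control (n = 7). Its probe maps to chromosome 6 at 41442725 to 41442759 in Gm10334, 41396717 to 41396751 in Gm5771 and 41374268 to 41374302 in Prss3 (GRCm38.p6), so its counts cannot be assigned to 1 of these trypsinogen genes. At 5 days 1810009J06Rik still lay at 4.09 ± 0.59, H4c17 at 1.75 ± 0.24 and the histone gene H2bc8 at 0.88 ± 0.17. Smaller rises were those of the interferon-inducible gene Ifi27 at 0.98 ± 0.086, the galectin gene Lgals9 at 0.84 ± 0.093 and the transcription factor gene Zbtb16 at 0.40 ± 0.084. The 3 falls were those of Ctrc at -1.54 ± 0.27, the hepcidin gene Hamp2 at -0.86 ± 0.14 and the myoglobin gene Mb at -0.61 ± 0.12.

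Digestive enzyme genes kept a lower mean at 5 days, with Ctrc the 1 called of 22 and 12 falls adjusted over the list alone (mean -1.02, camera adjusted p = 2.30e-19, adjusted p = 0.544 with an estimated correlation). The same held at 7 days, with 0 called and 2 falls adjusted over the list alone (mean -0.60, camera adjusted p = 8.33e-08, adjusted p = 0.645 with an estimated correlation). Pnlip lay at -1.72 ± 0.62 at 5 days and -1.02 ± 0.61 at 7 days, and Reg3b at 0.68 ± 0.63 and -0.033 ± 0.63, with no call. The acinar transcription factor and secretory list had a lower mean at 5 days (mean -0.24, camera adjusted p = 0.0268, adjusted p = 0.688 with an estimated correlation) and at 7 days (mean -0.24, camera adjusted p = 0.0458, adjusted p = 0.688 with an estimated correlation), and total-count scaling turned the sign at both times. Endoplasmic reticulum stress genes had 0 calls at 5 days and 2 rises adjusted over the list alone (mean 0.15, camera adjusted p = 0.0137, adjusted p = 0.688 with an estimated correlation). Immediate early genes had a higher mean (mean 0.18, camera adjusted p = 0.0268, adjusted p = 0.645 with an estimated correlation). Ribosomal protein genes had a higher mean at 5 days (mean 0.10, camera adjusted p = 0.0247, adjusted p = 0.963 with an estimated correlation). That mean was 0.0087 on array 1 and 0.19 on array 2. With total-count scaling camera reversed the direction (mean 0.53, adjusted p = 0.929). Their mean was also higher at 7 days (mean 0.27, camera adjusted p = 4.90e-12, adjusted p = 0.688 with an estimated correlation). Also called at 7 days were the islet list (mean 0.52, camera adjusted p = 0.0367, adjusted p = 0.700 with an estimated correlation) and the heat shock list (mean 0.19, camera adjusted p = 0.0415, adjusted p = 0.688 with an estimated correlation).

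At 5 days edgeR called 7 genes higher and 3 lower, with 202 at an unadjusted p under 0.05, where DESeq2 called 27, background subtraction gave 15 higher of 17 and total counts 60 of 65. Without the control sums there were 5 and 3 calls, and without either 5-day sum 5. At 7 days 200 genes had an unadjusted p under 0.05, DESeq2 called 13, and the call of Gm10334 ended without the array term and without any 1 of the 4 control and 7-day sums.

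The comparisons of 14 and 30 days with control asked how far the tissue had returned, and few genes were called. The edgeR test called 0 genes at 14 days, with 145 at an unadjusted p under 0.05, 12 called by DESeq2 and 1 by limma with the background subtracted. Pnlip lay at -0.42 ± 0.60 at 14 days and 0.037 ± 0.60 at 30 days, and at 33267 ± 4272 CPM at 30 days (SD, n = 7 regions). Krt8, Clu and Col1a1 lay at 0.097 ± 0.37, 0.061 ± 0.47 and -0.18 ± 0.36 at 30 days. The 1 gene called at 30 days was Nr1d2, which encodes a repressor of the circadian clock, at 0.67 ± 0.11 (adjusted p = 0.0418). Its differences at the earlier times went from 0.023 ± 0.13 at 3 hours to 0.61 ± 0.11 at 14 days.

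Regenerating and trefoil genes at 14 days had a higher mean with 0 calls and 3 rises adjusted over the list alone (mean 0.88, camera adjusted p = 3.41e-04, adjusted p = 0.645 with an estimated correlation). The list stood at 1.60 on array 1 and -0.35 on array 2, and at -0.21 without the 14-day sum of array 1. Reg3b lay at 3.54 on array 1 and -0.42 on array 2, and Reg2 at 2.89 and -1.25. Digestive enzyme genes still had a lower mean at 14 days, with 0 calls and 1 fall adjusted over the list alone (mean -0.44, camera adjusted p = 3.26e-06, adjusted p = 0.688 with an estimated correlation). They were not called at 30 days (mean -0.039, camera adjusted p = 0.696). The neutrophil list had a lower mean at 14 days (mean -0.16, camera adjusted p = 0.0381, adjusted p = 0.645 with an estimated correlation), which total-count scaling turned to 0.049. The immediate early list (mean 0.24, camera adjusted p = 6.51e-04, adjusted p = 0.544 with an estimated correlation) and heat shock list (mean 0.25, camera adjusted p = 0.00473, adjusted p = 0.645 with an estimated correlation) had higher means at 14 days. At 30 days the endoplasmic reticulum stress list had a higher mean (mean 0.20, camera adjusted p = 4.53e-04, adjusted p = 0.645 with an estimated correlation). It stood at 0.036 on array 1 and 0.35 on array 2. The immediate early list also had a higher mean (mean 0.16, camera adjusted p = 0.0211, adjusted p = 0.645 with an estimated correlation). The heat shock list did too (mean 0.27, camera adjusted p = 3.81e-04, adjusted p = 0.645 with an estimated correlation). Adjusted over the list alone, 1 gene each of the endoplasmic reticulum and heat shock lists rose.

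At 14 days there was 1 call without the control sum of array 1 and 2 without the 14-day sum of array 2. At 30 days 98 genes had an unadjusted p under 0.05 and DESeq2 called 4. The call of Nr1d2 ended by the 75th percentile, the negative probes, total counts and background subtraction, with each other filter on low counts, without the array term, without either control sum and without the 30-day sum of array 2. It held with DESeq2 and its size factors, with regions as samples and without the 30-day sum of array 1, where 2 genes were called.

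**Figure D4:**
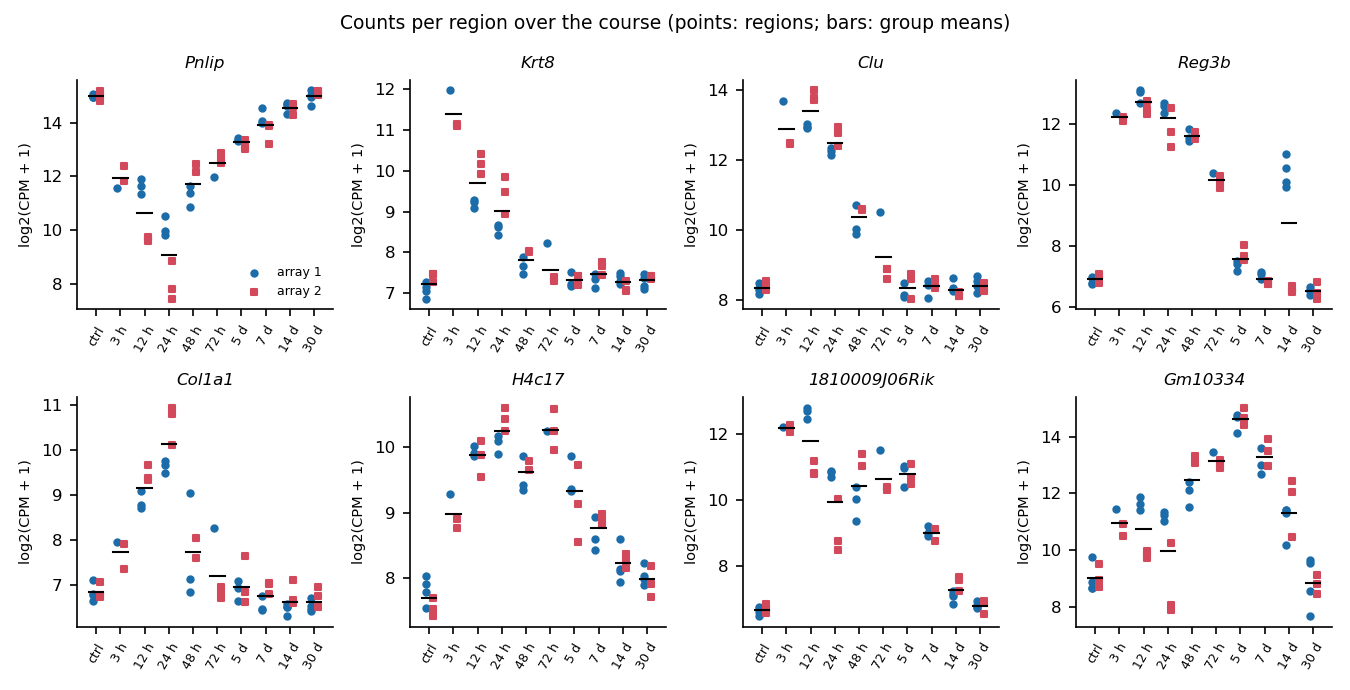
Level of 8 genes in each region, as log2(CPM + 1), by time point (ctrl, control), with points for regions coloured by array and a bar at each group mean. Pnlip fell to 703 CPM at 24 hours from 32781 in control and stood at 33267 at 30 days, and Reg3b at 14 days was high in the regions of array 1.

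The direct test of 72 hours against 12 hours, which uses no control, asked what differed between these times. Genes of the ductal and metaplasia list fell: Clu lay at -3.62 ± 0.53, Spp1 at -1.95 ± 0.38, Krt8 at -1.93 ± 0.38, Krt18 at -1.72 ± 0.32 and Krt19 at -1.23 ± 0.19. So did the matrix genes Col1a1 at -1.50 ± 0.37 and Col3a1 at -1.40 ± 0.30. Which cells carried these transcripts was not resolved. Enzyme transcripts rose, with Clps at 2.21 ± 0.47, Cel at 2.10 ± 0.56 and Zg16 at 1.99 ± 0.52. Pdia2 rose by 2.28 ± 0.30 and the acinar transcription factor gene Bhlha15 by 0.97 ± 0.25, while Nupr1 lay at -2.29 ± 0.39 and Xbp1 at -1.37 ± 0.22. Reg3b lay at -2.50 ± 0.65, and Tff2 rose by 1.55 ± 0.32.

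Of 22 digestive enzyme genes 11 rose, 13 adjusted over the list alone (mean 1.05, camera adjusted p = 1.22e-06, adjusted p = 0.688 with an estimated correlation). Ductal and metaplasia markers fell in 6 of 14 cases, 10 adjusted over the list alone (mean -1.04, camera adjusted p = 9.50e-07, adjusted p = 0.645 with an estimated correlation). Fibroblast and matrix genes fell in 8 cases and rose in 1 of 16, 9 and 1 adjusted over the list alone (mean -0.57, camera adjusted p = 2.02e-04, adjusted p = 0.654 with an estimated correlation). Macrophage markers fell in 2 of 10 cases, 2 adjusted over the list alone (mean -0.33, camera adjusted p = 0.0268, adjusted p = 0.688 with an estimated correlation), Ctss at -0.88 ± 0.19 and Lgals3 at -0.78 ± 0.13. Ribosomal protein genes fell in 8 of 74 cases, 4 adjusted over the list alone (mean -0.30, camera adjusted p = 0.00117, adjusted p = 0.914 with an estimated correlation). Rpl5 lay at -1.17 ± 0.27, and the list mean was 0.014 without the 72-hour sum of array 2. Endoplasmic reticulum stress genes rose in 2 of 15 cases, 3 adjusted over the list alone (mean 0.23, camera adjusted p = 0.0437, adjusted p = 0.699 with an estimated correlation). Herpud1 lay at 1.07 ± 0.24 and Hyou1 at 0.55 ± 0.14, and the list mean was -0.026 when scaled to the negative probes.

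Between 12 and 72 hours 223 genes were higher and 292 lower, 504 of the 515 with the same sign on both arrays. The 75th percentile gave 83 higher of 570, the negative probes 38 of 791, background subtraction 43 of 271 and total counts 35 of 191, with medians over all genes of -0.10, -0.26, -0.28 and -0.10. There were 64 calls without the 12-hour sum of array 2 and 12 without the 72-hour sum of array 2.

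The direct test of 30 days against 72 hours asked what differed late in the course. Secretory genes rose, with Sycn at 2.62 ± 0.40, Gp2 at 2.61 ± 0.36, Amy2a1 at 2.17 ± 0.50, Cela2a at 2.12 ± 0.50, Cela1 at 1.86 ± 0.40, Prss2 at 1.58 ± 0.36, Ctrc at 1.47 ± 0.27 and Tff2 at 1.92 ± 0.32. Regenerating genes fell, with Reg3b at -3.69 ± 0.69, Reg2 at -3.60 ± 0.71 and Reg3g at -1.36 ± 0.30. The trypsin-like target Gm10334 fell too, at -4.36 ± 0.68, as did H4c17 at -2.28 ± 0.24 and Stmn1 at -0.62 ± 0.13. Of 22 digestive enzyme genes 6 rose, 16 adjusted over the list alone (mean 1.31, camera adjusted p = 2.51e-24, adjusted p = 0.465 with an estimated correlation). Regenerating and trefoil genes fell in 3 cases and rose in 1 of 7, 4 and 1 adjusted over the list alone (mean -1.25, camera adjusted p = 5.96e-04, adjusted p = 0.645 with an estimated correlation). Ribosomal protein genes had 0 calls and 9 falls adjusted over the list alone (mean -0.50, camera adjusted p = 2.25e-23, adjusted p = 0.645 with an estimated correlation). The fibroblast and matrix list had a lower mean with 0 calls (mean -0.26, camera adjusted p = 0.00574, adjusted p = 0.688 with an estimated correlation). The acinar transcription factor and secretory list had a higher mean with Gnmt as its 1 call (mean 0.31, camera adjusted p = 0.00574, adjusted p = 0.645 with an estimated correlation), which total-count scaling turned.

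Between 72 hours and 30 days 14 genes were higher and 14 lower, with 322 at an unadjusted p under 0.05 and 127 called by DESeq2. Background subtraction gave 6 higher of 18, the negative probes 6 of 17 and total counts 13 of 1096, with medians over all genes of -0.17, -0.089 and -0.49. There were 55 calls without the 72-hour sum of array 2, 8 and 6 without the 30-day sums of array 1 and array 2, and 20 without the islet-rich 12-hour region.

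Across the 11 comparisons, 64 of the 176 list tests were called by camera with its preset correlation, 0 with an estimated correlation and 17 by fry, 16 of which were among the 64. The array itself differed in 778 genes (327 higher and 451 lower on array 2), with a median absolute log2 difference of 0.23 over these 778 genes, 10 of them beyond 2-fold. Nuclei per region exceeded control at 12, 24 and 48 hours and at 5 and 7 days (2-sided exact permutation tests, adjusted p = 0.00525, 0.0378, 0.0114, 0.0262 and 0.0262), and these p-values, taken over regions that may share tissue, are too small.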

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

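The tests weighed in the next 3 paragraphs, on the fall of the negative probes, the enzyme genes scaled to the negative probes, the 14-day tissue of array 1, and Gm10334 against Try4, Prss2, other scalings and its probe positions, were chosen only after the result was seen or when values already seen left little doubt of it.

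Reg3b and Reg2 differed between the arrays at 14 days, at 3.54 and 2.89 on array 1 against -0.42 and -1.25 on array 2 on the log2 scale. A tissue of an earlier time point under a wrong label would carry the other changes of 72 hours, but the median difference of the 26 other genes called at 72 hours was 0.33 in this sum against 1.505 and 1.467 on the arrays at 72 hours. Islet tissue, which expresses Reg genes, is argued against by a mean islet marker difference of -0.070, and 1 aberrant region by 4 of 4 regions above every control region in Reg3b. A difference between the animals or tissue pieces of the arrays at 14 days may lie behind the pattern and was not tested, since the labels tie no region to an animal. The other Reg genes were also higher on array 1. There Reg3g, Reg3d, Reg3a and Reg1 stood at 1.48, 1.2, 1.07 and 0.88, against 0.11, -0.12, -0.028 and -0.34 on array 2. Outside the regenerating and trefoil list, the sets compared here did not lie further from control on array 1. The 26 genes, none of them from that list, had a median of 0.46 on array 2 at 14 days. The enzyme list had a mean of -0.33 on array 1 and -0.55 on array 2.

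The Gm10334 target was higher than control from 48 hours to 7 days, with 5.50 at 5 days. Binding of its probe to the RNA of Try4 or Prss2 is argued against, because Gm10334 exceeded the higher of the pair by 5.61 at 5 days. Scaling shifts all genes together, and at 5 days it moved their median by no more than 0.43, with 5.50 as the lowest value of Gm10334 under 4 other scalings. The probe is annotated at 3 positions, in Gm10334, Gm5771 and Prss3, whose RNAs cannot be told apart with 1 probe, so each of these trypsinogen genes may be the source. A change in transcription of these genes during recovery stays open and was not tested.

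At 12 and 24 hours 565 and 552 genes were lower than control, while the negative probes lay at -0.41 and -0.43. Of these falls 12.7% and 10.9% went beyond the fall of the negative probes by more than 2 SE, so a lower background level against the scaled counts may account for most of them. For digestive enzymes it cannot account for the pattern, because 18 of the 22 genes at 12 hours and 20 at 24 hours remained lower when scaled to the negative probes. Real falls of weakly expressed genes stay open and were not tested apart from background.

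Regions that stood apart from the others of their group are given next as values. Of 180 groups tested over 20 measures 14 held such a region, where chance gives about 1 in 20 groups. For nuclei these were a 12-hour region of array 1 with 1275 against 1514 to 1623, a 48-hour region of array 1 with 1167 against 1649 to 1796, and a 14-day region of array 2 with 1371 against 1070 to 1196. The same 48-hour region had 1769 targets above 2 times background against 667 to 835. In mean log2 CPM of the islet markers the 12-hour region of array 1 stood at 10.3 against 6.29 to 7.65, the 14-day region of array 2 at 8.04 against 6.87 to 7.17, and a 72-hour region of array 2 at 6.68 against 6.82 to 6.84. At 72 hours an array 2 region stood at 11.6 against 11.3 in the enzymes, the array 1 region at 7.22 against 6.91 to 6.92 in the ductal markers, and an array 2 region at 6.94 against 6.87 to 6.88 in the proliferation genes. A 24-hour region of array 2 stood at 7.91 against 6.95 to 7.23 in the macrophage markers and a 5-day region of array 2 at 6.89 against 6.61 to 6.70 in the matrix genes. A control region of array 2 stood at 6.52 against 6.70 to 6.81 in the proliferation genes and a 30-day region of array 2 at 7.26 against 7.10 to 7.16 in the heat shock genes.

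The effects of 2 time points differed in a direct test of the difference for 515 genes between 12 and 72 hours and for 28 between 72 hours and 30 days. In the first test, by camera with its preset correlation and in none of the 6 lists with an estimated one, the list means differed by 1.05 for digestive enzymes, -1.04 for ductal markers, -0.33 for macrophage markers, -0.57 for matrix genes, 0.23 for endoplasmic reticulum stress genes (-0.026 when scaled to the negative probes) and -0.30 for ribosomal proteins, the last at 0.014 without the 72-hour sum of array 2. In the second they differed by 1.31 for digestive enzymes, 0.31 for acinar transcription factors and secretory genes, -0.26 for matrix genes, -1.25 for regenerating and trefoil proteins and -0.50 for ribosomal proteins, where total counts turned the acinar list to -0.16. With an estimated correlation 0 of these 11 list differences were called.

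Nuclei per region, which entered no comparison of genes, exceeded the control mean of 941.6 with 1512 at 12 hours, 1355.7 at 24 hours, 1626.4 at 48 hours, 1277.7 at 5 days and 1262.5 at 7 days. The 2-sided exact permutation tests gave adjusted p = 0.00525, 0.0378, 0.0114, 0.0262 and 0.0262, values that are too small because regions may share tissue. At 3 hours, 72 hours, 14 days and 30 days the means were 1283, 1221, 1166.9 and 1095.1 with adjusted p = 0.131, 0.125, 0.0664 and 0.242 in the same exact tests. The 72-hour mean includes the larger region of array 1, with 959 nuclei over 509054 µm², and nuclei were not corrected for area.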

How the results depend on the processing

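The filter at the deposited limit of quantitation, the scaling to the negative probes and the runs without Lrr1 or without the islet-rich 12-hour region were tests chosen only after the results were seen. Counts below are genes called, in the order 3, 12, 24, 48 and 72 hours, 5, 7, 14 and 30 days against control, 72 against 12 hours, 30 days against 72 hours, and any change, where a count moved by more than 1.5 times.

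Total counts without TMM gave 1558, 2223, 2306, 2494 and 2281 genes from 3 to 72 hours, 65, 8 and 5 at 5, 7 and 14 days, 191 and 1096 in the direct tests and 2238 for any change. The stricter filter, with fewer genes tested, gave 172, 476 and 471 at 3, 12 and 24 hours, 0 at 30 days, 173 and 69 in the direct tests and 453 for any change. No filter, with more genes tested, gave 1920 and 2060 at 12 and 24 hours, 2 at 7 days, 0 at 30 days and 1961 for any change, and the deposited limit of quantitation gave 1920, 2055, 2, 0 and 1951 for the same results. Without the array term there were 704, 652 and 26 genes at 12, 24 and 48 hours, 0 at 7 days, 0 at 30 days, 231 and 16 in the direct tests and 587 for any change. DESeq2 called 117 and 81 at 48 and 72 hours, 27, 13, 12 and 4 at 5, 7, 14 and 30 days and 127 between 72 hours and 30 days. Subtraction of the negative-probe level gave 543 at 3 hours, 58 at 72 hours, 17, 6 and 1 at 5, 7 and 14 days, and 271 and 18 in the direct tests. Scaling to the negative probes gave 1773 at 24 hours, 26 at 48 hours, 0 at 30 days, and 791 and 17 in the direct tests, and the 75th percentile gave 0 at 30 days. Of the 64 called list tests an estimated correlation left 0 and fry called 17 tests. DESeq2 size factors and the run without Lrr1 moved none of these counts by more than 1.5 times. Apart from the filters, whose number of genes tested differs, the cause was not tested.

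With each region as a sample there were 615, 488 and 268 genes at 3, 48 and 72 hours, 217, 203, 140 and 102 at 5, 7, 14 and 30 days, 1320 and 296 in the direct tests and 2122 for any change. A random block of time point and array gave 197 and 124 at 48 and 72 hours, 56, 43, 23 and 13 from 5 to 30 days, and 806 and 196 in the direct tests, with a correlation of 0.25 between regions of one sum. With the replicate number as a replicate block there were 539, 429 and 146 genes at 3, 48 and 72 hours, 170, 158, 133 and 98 from 5 to 30 days, 1098 and 213 in the direct tests and 2068 for any change, and 1626 and 1646 at 12 and 24 hours. The numbers do not pair regions: over 223 pairs of the same number the mean correlation was -0.018, against 0.0036 for other pairs. For 1 of 57 regions the mean correlation with regions of other groups was highest for its own number. Apart from the random block, these counts treat regions that may share tissue as independent.

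Leaving out 1 sum at a time gave 118 to 472 genes at 3 hours, 280 to 1115 at 12 hours, 256 to 1189 at 24 hours, 10 to 26 at 48 hours, 5 to 61 at 72 hours, 3 to 5 at 5 days, 0 to 1 at 7 days, 0 to 2 at 14 days and 0 to 2 at 30 days. In the direct tests it gave 12 to 637 and 6 to 55, for any change 927 to 1269, and of the list tests 51 to 67 were called. A group then has 1 sum, which is assumed to vary like the other groups.

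Directions of single genes reversed under 2 scalings. With total counts these were Dnajc3 at 0.063 and Relb at 0.18 at 3 hours, and at 12 hours Il1r2 at 0.33, Retnlg at 0.45, Ccnb1 at 0.43, Herpud1 at 0.054, Edem1 at 0.097, Nfkbia at 0.40 and Hsph1 at 0.20. At 24 hours they were Rab3d at 0.29, Mafa at 0.38, Il1r2 at 0.42, Retnlg at 0.46, Edem1 at 0.22, Cfd at 0.026, Hsph1 at 0.39 and Insig1 at 0.34, and at 48 hours Gnmt at 0.095. Scaled to the negative probes, Retnlg stood at 0.11, Ccnb1 at 0.088 and Nfkbia at 0.060 at 12 hours, and Mafa at 0.017, Il1r2 at 0.045, Retnlg at 0.096 and Hsph1 at 0.015 at 24 hours. Of the called lists, ribosomal proteins at 5 days reversed in camera with total counts (mean 0.53), regenerating and trefoil proteins at 14 days without the 14-day sum of array 1 (-0.21, against 1.45 without that of array 2), and ribosomal proteins between 12 and 72 hours without the 72-hour sum of array 2 (0.014, against -0.62 without that of array 1). List means also changed sign where camera, which compares a list with the other genes, kept the direction. With total counts these were the acinar transcription factor and secretory list, at 0.016, 0.36, 0.28, 0.33 and 0.285 from 3 to 72 hours, 0.19 at 5 days, 0.14 at 7 days and -0.16 between 72 hours and 30 days, and the neutrophil list at 14 days (0.049). With the negative probes they were the acinar list at 12 hours (0.023) and the endoplasmic reticulum stress list between 12 and 72 hours (-0.026). Of the 214 named changes, 201 kept their call and 13 lost it by the 75th percentile, 211 kept it with DESeq2, 214 with DESeq2 size factors and without Lrr1, 177 without the array term, 188 scaled to the negative probes and 185 with total counts. Over the runs without 1 sum, 586 kept the call and 270 lost it. As ratios to the negative probes, the 10 highest control levels moved by less than 1 SD with the deposited signal and without each control region. Neither check could have failed. The deposited signal applies 1 factor per region, which leaves the ratio unchanged, and leaving out 1 of 7 regions cannot move a mean by 1 SD.

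Background limits these results at the weak end: genes near the negative probes cannot fall far, and 2688 of 9780 targets were tested. Depth alone did not set this limit. Array 2, the deeper, had a median of 670 targets per region above 2 times background, against 829 on array 1. With 2 sums per group, of 1 region each for 3 hours and 72 hours on array 1, small differences after 48 hours could be missed even where the simulated 1.5-fold changes were recovered in 57 of 67 cases at 24 hours.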

Other observations

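The test of the histone genes was chosen only after the result was seen, and the reassignment of the sums to groups before. Trypsinogen targets of the cluster on chromosome 6 moved in opposite directions, a contrast chosen after its values were seen. Prss2 lay at -1.51 ± 0.36 at 3 hours and -2.31 ± 0.37 at 24 hours (log2 difference from control ± SE, n = 2 sums), and Try4, whose probe maps to Try4, Try5 and Try10, lay at -1.79 ± 0.43 at 12 hours and -2.46 ± 0.44 at 24 hours. Gm10334 was already higher at 3 hours, at 1.95 ± 0.61, and at 12 hours, at 1.80 ± 0.61 (2.60 on array 1 and 0.61 on array 2). At 5 days Gm10334 was at its highest value while Prss2 stood at -1.64 ± 0.36 and Try4 at -0.11 ± 0.42, neither called.

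Replication-dependent histone genes, whose transcripts accumulate in S phase, rose from 3 hours and were highest at 24 hours by their median. Of 10 such targets tested, 6 of them with probes at 2 to 11 annotated positions so that single genes cannot be told apart, 3 were higher at 3 hours, 7 at 12 hours, 10 at 24 hours, 5 at 48 hours, 7 at 72 hours and 2 at 5 days, and 0 were lower at these times. Their median log2 difference was 0.42, 0.92, 1.40, 0.67, 1.07 and 0.59 at those times, and 7 fell between 72 hours and 30 days, with a median of -1.15. Between 12 and 72 hours H4c17, whose probe maps to 3 histone H4 genes on chromosome 13, stood at 1.95 to 2.60 and H2bc8 at 1.05 to 1.74. A candidate explanation is that more cells were in cycle: 10 of 10 histone genes and Stmn1 were higher at 24 hours. However, Ccnb1 was lower at 12 hours (but at 0.43 with total counts and 0.088 scaled to the negative probes). Pcna and Ccnd1 were tested and not called at 24 hours. The proliferation list had 14 targets in the deposited table, and all but Stmn1, Ccnb1, Pcna and Ccnd1 failed the filter on low counts. Dazl, counted among the 14, was not on the fixed list and was matched only through a synonym. The other genes of the fixed list were not among the targets and could not be tested. The cell type that carries these transcripts was not tested.

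Chance as the source of the genes that differ between any of the 10 groups can be excluded at this level, because 1 of 100 assignments of the sums to groups within arrays, the real one, gave as many genes. The real assignment gave 1131 genes, the highest of the others 723 and their median 0.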
